A study of Oryza sativa with 6 samples.

How the data were processed

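Leaf RNA of rice (Oryza sativa) was measured on 6 Agilent rice oligonucleotide arrays, 3 for the genotype Apo and 3 for the genotype IR64. Each array carried a pair of labelled RNAs of 1 genotype, well-watered leaves in the Cy5 channel and drought-stressed leaves in the Cy3 channel, and no array had the dyes exchanged, per the labels. Total RNA was extracted with TRIzol and labelled with a linear amplification kit for small RNA amounts, per the labels' protocols. Nothing in the labels says whether the replicates of a genotype are separate plants, so the p-values measure only the spread between these samples, which may be technical.

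The deposited values are within-array log ratios made with Agilent Feature Extraction 8.1, per the submitters' processing notes. They are taken here as log10, the base that this software writes; the base is not recorded with the values. The sign of the ratio, the dye normalization, the background correction and the centring are not given in the sources used here either. The median of the deposited log10 ratios was 0.0020 on the Apo replicate 1 array and 0.0000 on each of the other 5 arrays. P-values and the counts of calls by p-value alone do not depend on the base, while folds and the counts with a 2-fold minimum hold only if the base is 10. Channel intensities were not used here, so how far a probe lay above background is unknown, and the number of arrays limits the precision.

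The value table held 22575 spots. The platform annotation gave a gene for 17860 of them, 1 gene for 17839 and several for 21, and none for 4715. All 17839 gene identifiers were found in the gene table, which belongs to the assembly ASM3414082v1 of Oryza sativa Japonica Group and was used for names only. Spots at exactly 0 on all 6 arrays, 133 in number, were left out, and 17727 annotated probes were tested. A gene is named by a synonym of the gene table where it has one, which held for 2411 probes of 2110 genes.

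Ratios were used as deposited, with no further normalization. The written plan had assumed a log2 scale. It was also departed from in the gene lists and in the rule for named genes, as given below. A linear model with 1 mean per genotype was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, followed by eBayes and limma's moderated test, and p-values were adjusted over probes by the Benjamini-Hochberg method at a threshold of 0.05. The contrasts were Apo against 0, IR64 against 0, Apo minus IR64, and the mean of both genotypes. Standard deviations are over the 3 arrays of a genotype. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

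The tests, the thresholds, the themes of 28 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 28 themes were written as patterns over gene descriptions, but the tables used here pair probes with gene names only, and 18 patterns had no match. The lists were therefore redrawn as sets of gene names, and 20 lists of name families present on the array were added, both before any ratio was looked at. The redrawn lists do not match the 28 themes exactly. Calvin cycle and plastid ribosomal proteins got no list, and the abscisic acid theme was narrowed to receptors, kinases, phosphatases and factors. The cell wall theme was split into expansins and cellulose synthases, and the jasmonate theme into jasmonate genes and chitinases with pathogenesis-related proteins. Of the 48 lists, 47 had at least 5 probes and were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Fry tests whether the genes of a list move, on balance, one way, without comparing them with other genes.

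The rule for named genes took probes past the threshold with 1 gene, a gene name, and the same sign on all 3 arrays of the genotype, or, for the difference, no overlap between the genotypes' arrays. Among these the 8 largest on each side were named with 1 probe per gene, and the rule added the 3 members with the smallest p-value of each list that camera called or that had 3 or more called members. The report gives these members for the lists that camera called, and the closing section gives a selection of the rest. The plan asked for a gene description; a gene name other than an identifier took its place. The markers RAB16A, LEA3, NCED3 and SNAC1 matched no name in the tables used here, while P5CS and DREB1A did. Different probes of a gene were kept apart, and the text says where those of a named gene disagree. Of 1832 genes with several probes, 533 had several called probes in Apo, and 96 of these had calls on both sides; in IR64 91 of 398 did, and for the difference 0 of 4.

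The replicate numbers were checked for pairing before the calls were compared. The deviations of same-numbered Apo and IR64 arrays from their genotype means correlated across probes at 0.322, 0.261 and 0.340, and those of other pairs at between -0.260 and 0.0166. All 3 same-number correlations lay above 0.1, so the numbers were taken to pair the arrays, on the evidence of the data and not of the labels. Deviations from a genotype mean cancel over its arrays. The low values of the other pairs therefore follow in part from the same-number ones and are no separate evidence. The fit without a block had been fixed beforehand and stayed the main one. The fit with the replicate number as a block was an alternative.

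The fit was tested on simulated data with 200 of 17727 probes changed. For Apo it recovered 0% of changes of 0.2 on the log10 scale, 73.5% of 0.4 and 95% of 0.8. For Apo minus IR64 it recovered 0%, 52.5% and 85%. False calls numbered 0, 7 and 10 for Apo and 0, 2 and 12 for the difference. The simulated noise was independent between probes, and far fewer probes changed than the 8890 called in Apo. The adjusted threshold for Apo was therefore harder to pass than in the data, so these shares do not give the recovery of the real fit. The other alternatives were median centring, centring with scaling to 1 spread, robust eBayes, unmoderated tests, array weights, each genotype fitted alone, averaging over the probes of a gene, only probes with no 0 on any array, a 2-fold minimum (if the base is 10), and leaving out each array in turn. Testing all spots of the table was chosen after seeing the data.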

Results

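The transcript levels of drought-stressed and well-watered leaves were compared within 2 rice genotypes, Apo, which the submitters describe as tolerant of drought, and IR64, which they describe as susceptible. Water was withheld from 33 days after sowing in the greenhouse, and stressed leaves were sampled after 5 days by the sample labels and after 6 days by the series text. Control leaves were harvested on day 37. By these days the stressed and control leaves may have been harvested at different ages, and an effect of that would stay in every ratio. Each genotype had 3 arrays, and every array gave 1 ratio per probe between its stressed and its control RNA. Because the sources used here do not state which RNA is the numerator, ratios are described as positive or negative and not as higher or lower in drought. Values are deposited log10 ratios, with the base taken from the software, given as mean ± SD over 3 arrays.

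The first comparison asked which genes had unequal levels in stressed and control leaves of Apo. LEA proteins and dehydrins, which protect cells during water loss, had the highest median of the 48 gene lists, 1.27, and all 6 members were positive past the threshold. RAB16C stood at 1.72 ± 0.107, rab25 at 1.15 ± 0.0757 and Dhn1 at 0.935 ± 0.191. Proteins of abscisic acid signalling, the hormone pathway of water deficit, were mostly on the same side. Photosystem proteins, enzymes of chlorophyll synthesis and circadian clock components were mostly negative.

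Of the 21 probes for abscisic acid receptors, kinases, phosphatases and factors, 16 were positive, 2 negative and 3 not past the threshold, or 17 and 2 adjusted over the list alone. SAPK1, a kinase of the SnRK2 family, stood at 1.26 ± 0.0563, the phosphatase PP2C30 at 0.775 ± 0.00987 and the kinase SAPK4 at 0.648 ± 0.0606. Camera gave this list an adjusted p = 0.000391, against an adjusted p = 0.557 with an estimated correlation. The LEA and dehydrin list, with 6 positive members also adjusted over the list alone, had a camera adjusted p = 0.00165 and an adjusted p = 0.427 with an estimated correlation. Small heat shock proteins, HSP90 and ClpB, which keep other proteins from aggregating, had 11 positive and 2 negative probes of 19, the same numbers adjusted over the list alone. HSP18.0 was at 1.03 ± 0.0121, although its second probe was at 0.0275, HSP26.7 was at 1.29 ± 0.157 and HSP22.3 went the other way at -0.910 ± 0.0512. Their camera adjusted p = 0.0154 became an adjusted p = 0.427 with an estimated correlation. CCCH zinc finger proteins had 22 positive and 3 negative probes of 55, among them OsC3H37 at 1.25 ± 0.194, OsC3H35 at 0.644 ± 0.00592 and OsC3H2 at 0.542 ± 0.117. The list had a camera adjusted p = 0.0394 and an adjusted p = 0.427 with an estimated correlation.

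On the negative side, 10 of 11 probes for photosystem and electron transport proteins passed the threshold, the same number adjusted over the list alone, and none was positive. The light-harvesting genes CAB2R and RCABP69 stood at -1.12 ± 0.266 and -1.08 ± 0.0470, and OEE3, of the oxygen-evolving complex, at -0.626 ± 0.0864. Camera gave an adjusted p = 0.00307, against an adjusted p = 0.684 with an estimated correlation. Enzymes of chlorophyll synthesis had 10 negative and 1 positive probe of 14, the same numbers adjusted over the list alone. CHLH and CHLD, subunits of the enzyme that inserts magnesium, were at -0.607 ± 0.0204 and -0.252 ± 0.0377, and HEMD was at -0.348 ± 0.0459. Their camera adjusted p = 0.0231 became an adjusted p = 0.733 with an estimated correlation. Of 8 clock probes, 6 were negative and none positive, with the response regulators PRR37 at -0.600 ± 0.0359, PRR95 at -0.305 ± 0.0510 and PRR73 at -0.345 ± 0.0277. The list had a camera adjusted p = 0.0401 and an adjusted p = 0.508 with an estimated correlation. All 7 of these lists were also called by fry, which called 33 of the 47 tested lists in Apo and so sets them little apart.

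The largest positive ratios among named genes of Apo belonged to LTI6B, a small hydrophobic membrane protein, at 1.98 ± 0.0672, and OsPM19L1, at 1.96 ± 0.130, a ratio of 92.1 if the base is 10. After RAB16C came the germin-like GER2 at 1.66 ± 0.206, isocitrate lyase (ICL) at 1.63 ± 0.0996, ELA3 at 1.63 ± 0.0274, the heat shock factor HSFA6B at 1.61 ± 0.0476 and the phosphatase OsPP2C59 at 1.58 ± 0.0449. The largest negative ratio was that of LIS, linalool synthase, at -1.71 ± 0.0927, followed by the metallothionein MT2B at -1.56 ± 0.0365. The next were the translation factor eIF-4G at -1.42 ± 0.117, OsPHO1;3 of a phosphate transporter family at -1.40 ± 0.292, and CAD6, a cinnamyl alcohol dehydrogenase, at -1.33 ± 0.0324. Nitrate reductase NIA1 followed at -1.33 ± 0.176, the actin-binding ADF-7 at -1.28 ± 0.0713 and the sugar transporter SWEET2B at -1.23 ± 0.0528. Other probes disagreed for eIF-4G, whose remaining 4 stood between 0.0504 and 0.282, for NIA1, whose second stood at 0.278, and for MT2B, whose second stood at -0.175. Of the markers named in advance, P5CS2, a proline synthesis enzyme, was positive at 0.641 ± 0.0830 and 0.420 ± 0.262 on its probes, and DREB1A had a mean of 0.00576 ± 0.196, not past the threshold.

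In Apo, 8890 of 17727 probes passed limma's test at the adjusted threshold, 4350 positive and 4540 negative, and 8855 of them had 1 sign on all 3 arrays. Markers of other cell types were not called by camera: root markers had 5 positive and 6 negative probes of 28 (adjusted p = 0.828), vascular and secondary wall markers 4 and 2 of 14 (0.687), anther markers 3 and 0 of 6 (0.582) and seed storage proteins 1 and 0 of 5 (0.859). Fry called the root markers (adjusted p = 0.0458) and the anther markers (0.0376). The clock call was lost without Apo replicate 1 (adjusted p = 0.0567), without Apo replicate 3 (0.0560) and with the replicate number as a block (0.0755), and the CCCH call without IR64 replicate 1 (0.0578), without IR64 replicate 2 (0.0530) and with the block (0.0676). Lipid transfer proteins gained a call without Apo replicate 1 (0.0435), against an adjusted p = 0.557 with an estimated correlation on all arrays. A dye effect would stay in every ratio of a genotype, since no array had the dyes exchanged.

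The second comparison asked the same of IR64. LEA proteins and dehydrins again had the highest median of the lists, 1.06, with 5 of 6 members positive past the threshold and 6 adjusted over the list alone. RAB16C was at 1.43 ± 0.210, rab25 at 0.851 ± 0.174 and Dhn1 at 0.685 ± 0.0280. Lipid transfer proteins and glutathione S-transferases were also on the positive side, and MADS box factors, circadian clock components, aquaporins and photosystem proteins mostly on the negative side. The LEA and dehydrin list had a camera adjusted p = 0.00643 and an adjusted p = 0.352 with an estimated correlation.

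Of 6 probes for lipid transfer proteins, which carry lipids and wax precursors, 5 were positive and none negative, also adjusted over the list alone. LTP-2 stood at 0.841 ± 0.0207, LTP2-A at 1.07 ± 0.0868 and LTP2-B at 1.02 ± 0.112. Of 8 probes for glutathione S-transferases, detoxifying enzymes, 5 were positive and none negative, also adjusted over the list alone, with GSTU6 at 0.40 ± 0.0277, GST-I at 0.583 ± 0.213 and gst2 at 0.158 ± 0.0657. A further GSTU6 probe was not past the threshold at 0.0892. For each of these lists the camera adjusted p = 0.0269 became an adjusted p = 0.362 with an estimated correlation. Of 29 probes for aquaporins, the water channels of cell membranes, 14 were negative and 3 positive, also adjusted over the list alone. PIP2-7, PIP2-2 and PIP1-3, of the plasma membrane family, stood at -1.01 ± 0.0213, -0.933 ± 0.130 and -0.702 ± 0.0689. Their camera adjusted p = 0.0269 became an adjusted p = 0.352 with an estimated correlation, and an adjusted p = 0.0556 with the replicate number as a block.

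Of 24 MADS box factors, which include regulators of flowering, 13 were negative and 2 positive in IR64, with MADS55 at -0.600 ± 0.0491, MADS58 at -0.541 ± 0.0188 and MADS50 at -0.446 ± 0.0621. Of 8 clock probes, 7 were negative and none positive, with PRR37 at -0.619 ± 0.0522, PRR95 at -0.341 ± 0.0559 and PRR73 at -0.373 ± 0.128. For each of these lists the camera adjusted p = 0.00643 became an adjusted p = 0.352 with an estimated correlation. Of 11 photosystem probes, 6 were negative and none positive, also adjusted over the list alone, with CAB2R at -1.22 ± 0.199, RCABP69 at -0.795 ± 0.307 and OEE3 at -0.366 ± 0.170. The list had a camera adjusted p = 0.0269 and an adjusted p = 0.666 with an estimated correlation. All 7 lists called in IR64 were also called by fry, which called 29 of the 47 tested lists there. Abscisic acid signalling, with 10 positive and 1 negative probe of 21 and 11 and 2 adjusted over the list alone, was not called by camera in IR64 (adjusted p = 0.0502), but was without Apo replicate 2 (0.0494), IR64 replicate 2 (0.0418) or IR64 replicate 3 (0.0216). With an estimated correlation it had an adjusted p = 0.677. Jasmonate synthesis and signalling, also at 0.0502, was called without Apo replicate 2 (0.0494) or IR64 replicate 3 (0.0459), against an adjusted p = 0.362 with an estimated correlation.

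The largest positive ratios among named genes of IR64 were those of OsPM19L1 at 1.77 ± 0.165, RAB16B at 1.48 ± 0.566 and RAB16C, followed by ELA3 at 1.42 ± 0.0397, the sugar transporter SWEET15 at 1.28 ± 0.0242, LTI6B at 1.28 ± 0.337, OsPP2C59 at 1.28 ± 0.0752 and RAB16D at 1.27 ± 0.303. The largest negative ratios were those of MT2B at -1.55 ± 0.0180, eIF-4G at -1.49 ± 0.123 and CAB2R. CRSH2, which makes the chloroplast alarmone ppGpp, stood at -1.21 ± 0.0550, ADF-7 at -1.19 ± 0.0572, the thioredoxin OsTrx03 at -1.18 ± 0.0823, mfs1 at -1.12 ± 0.0613 and SWEET2B at -1.03 ± 0.0782. Other probes disagreed for MT2B, whose second stood at 0.0852, and for eIF-4G, whose remaining 4 stood between -0.0712 and 0.184. P5CS2 was positive at 0.451 ± 0.134 on 1 probe and not past the threshold at 0.265 ± 0.231 on the other, which passed it with the replicate number as a block. DREB1A was negative at -0.596 ± 0.0475.

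In IR64, 7619 of 17727 probes passed the threshold, 4031 positive and 3588 negative, and 7596 of them had 1 sign on all 3 arrays; without IR64 replicate 2 the count was 5076. Root markers had 2 positive and 10 negative probes of 28 (camera adjusted p = 0.0762, 0.0425 with the replicate number as a block, and 0.362 with an estimated correlation), vascular and secondary wall markers 5 and 2 of 14 (0.634), anther markers 1 and 0 of 6 (0.905), and seed storage proteins no call among 5 (0.634). Fry called the root markers (adjusted p = 0.00572) and the vascular and secondary wall markers (0.0392). The IR64 replicate 1 array correlated across probes at 0.832 to 0.894 with the Apo arrays and at 0.755 to 0.767 with the other IR64 arrays. Without it the calls for lipid transfer proteins (adjusted p = 0.0654) and photosystem proteins (0.0722) were lost, and without IR64 replicate 2 the call for glutathione S-transferases (0.0511). Without IR64 replicate 1, cytosolic ribosomal proteins (0.294 on all arrays, 0.0115 without it) and protein disulfide isomerases and ER chaperones (0.0940, 0.0235) were called; with an estimated correlation on all arrays they had an adjusted p = 0.874 and 0.677.

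**Figure D1:**
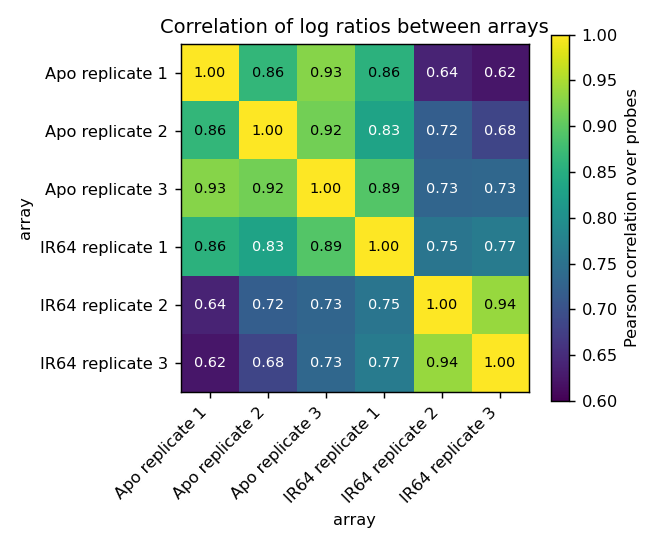
Pearson correlation of the log10 ratios of 17727 probes between each pair of the 6 arrays, by genotype and replicate. The IR64 replicate 1 array correlates at 0.832 to 0.894 with the Apo arrays, while the other IR64 arrays correlate with them at 0.624 to 0.734.

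The third comparison asked which ratios differed between the tolerant and the susceptible genotype, and a dye effect common to all arrays cancels in it. The cold and drought regulators DREB1B and DREB1A were near 0 in Apo, at 0.00331 ± 0.0322 and 0.00576 ± 0.196, and negative in IR64, at -0.848 ± 0.0411 and -0.596 ± 0.0475. Channel intensities were not used, so whether these and other genes near 0 in 1 genotype lay above background there is unknown. The SnRK2 family kinase SAPK1 was positive in both genotypes and more so in Apo, at 1.26 ± 0.0563 against 0.693 ± 0.165. Linalool synthase (LIS) was more negative in Apo than in IR64, at -1.71 ± 0.0927 against -0.374 ± 0.156. Among named genes GER2 had the largest positive difference, 1.66 ± 0.206 in Apo against 0.285 ± 0.366 in IR64.

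The difference of GER2 (LOC4344839) was 1.38 with a limma adjusted p = 0.0332, that of DREB1B (LOC4347618) 0.851 with 0.00600, and that of DREB1A (LOC4347620) 0.602 with 0.0423. The other named genes with the largest positive differences were the auxin response factor ARF16 (0.774, adjusted p = 0.0488), MADS14 (0.615, 0.0311), the chitinase chia4a (0.604, 0.0391), the homeodomain factor HOX24 (0.589, 0.0310) and SAPK1 (0.564, 0.0389). MADS14 and chia4a were at 0.0132 ± 0.0228 and -0.131 ± 0.0804 in Apo and at -0.602 ± 0.167 and -0.735 ± 0.173 in IR64. HOX24 stood at 1.37 ± 0.0352 in Apo and 0.779 ± 0.153 in IR64, and ARF16 at 1.03 ± 0.279 and 0.259 ± 0.0709.

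On the other side, LIS (LOC4328124) had a difference of -1.33 (adjusted p = 0.00600), and PAL06, a phenylalanine ammonia-lyase, of -1.14 (0.0318), with -0.856 ± 0.315 in Apo and 0.283 ± 0.129 in IR64. The other largest negative differences among named genes were those of BURP17 (-0.755, adjusted p = 0.0234), CAD6 (-0.697, 0.0244), the ethylene receptor ETR3 (-0.654, 0.0478), rpl5 (-0.617, 0.0290), the thioredoxin OsCiTrx (-0.597, 0.0203) and URH2 (-0.543, 0.0244). OsCiTrx and rpl5 were near 0 in Apo, at 0.00954 ± 0.0901 and -0.0286 ± 0.124, and positive in IR64, at 0.607 ± 0.0595 and 0.589 ± 0.0991. CAD6 was negative in both genotypes, at -1.33 ± 0.0324 in Apo and -0.635 ± 0.163 in IR64. A second probe for ETR3 showed no such difference, with -0.0357 in Apo and -0.0210 in IR64. P5CS2 did not pass the threshold for the difference on either probe (adjusted p = 0.187 and 0.549).

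**Figure D2:**
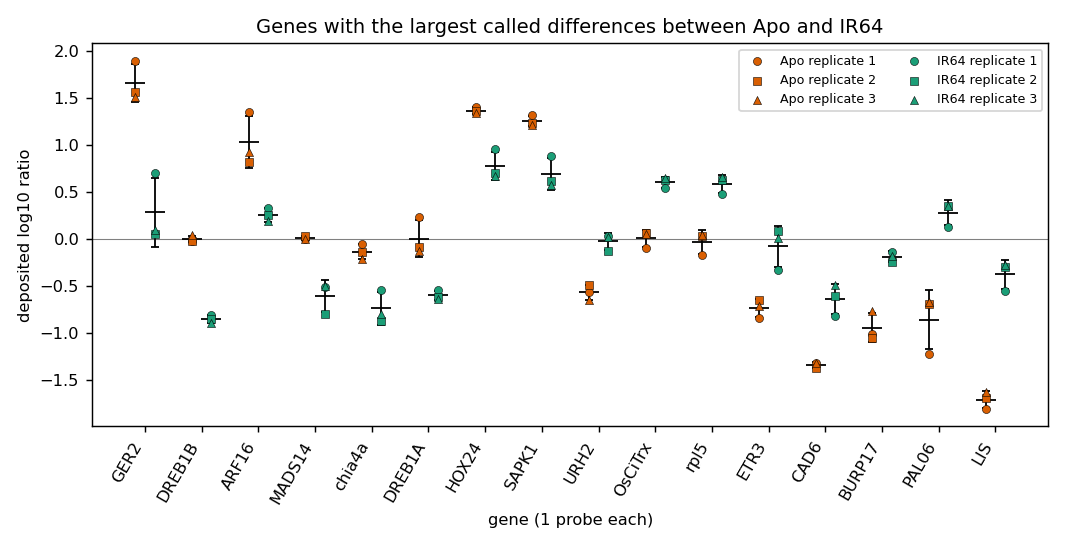
Deposited log10 ratio on each of the 6 arrays for the 8 named genes with the largest positive and the 8 with the largest negative difference, with symbols for arrays and bars for mean ± SD (n = 3). DREB1B lies near 0.00331 in Apo and near -0.848 in IR64, and LIS near -1.71 and -0.374.

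Among gene groups, abscisic acid signalling had more positive ratios in Apo, with a median difference of 0.197, 1 called probe of 21, and 10 positive and none negative adjusted over the list alone. The list medians were 0.378 in Apo and 0.174 in IR64, so a wider scale of the Apo arrays, given below, may enter this difference. Besides SAPK1 the smallest p-values were those of OsPP2C09, at 0.363 in Apo and 0.0140 in IR64, and BZIP23, at 0.596 and 0.174, neither past the threshold over all probes. Camera gave an adjusted p = 0.000109, against an adjusted p = 0.650 with an estimated correlation. NAC and DREB factors had a median difference of 0.228 and 2 called probes of 17, also adjusted over the list alone, both DREB1 genes; DREB1G was at -0.228 in Apo and -0.729 in IR64, not past the threshold. Their camera adjusted p = 0.000572 became an adjusted p = 0.650 with an estimated correlation. Within IR64 the median of this list was 0.0552 and its mean -0.0636. Chlorophyll synthesis had a median difference of -0.216 with no called probe of 14, and 5 negative adjusted over the list alone, led by GSA, CHLD and URO-D2, of which URO-D2 was at -0.367 in Apo and -0.00633 in IR64. A second GSA probe was not past the threshold on either count, at 0.310 in Apo and 0.132 in IR64, against 0.0778 and 0.362 on the first. Its camera adjusted p = 0.0145 became an adjusted p = 0.773 with an estimated correlation.

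Small heat shock proteins had a median difference of 0.0770, no called probe of 19, and 4 positive and 1 negative adjusted over the list alone. CLPB-C was at 0.241 in Apo and -0.0436 in IR64, HSP18.6 at 0.629 and 0.267, and HSP17.9B went the other way at -0.431 and 0.0166. The list had a camera adjusted p = 0.0179 and an adjusted p = 0.610 with an estimated correlation. Cytosolic ribosomal proteins had a median difference of -0.202 and no called probe of 17 on either count, with RPL18 at 0.00585 in Apo and 0.535 in IR64, RPL30 at -0.0376 and 0.231, and RPS21 at -0.0532 and 0.259. Their camera adjusted p = 0.0179 became an adjusted p = 0.807 with an estimated correlation. Heat shock factors had a median difference of 0.153 and no called probe of 19, with HSFA6B at 1.61 in Apo and 1.12 in IR64, HSFC2A at 0.776 and 0.469, and HSFC1A the other way at -1.07 and -0.532. The list had a camera adjusted p = 0.0308 and an adjusted p = 0.773 with an estimated correlation. MADS box factors had a median difference of 0.0815 and 2 called probes of 24, MADS14 and MADS58, followed by MADS26 at -0.00808 in Apo and -0.188 in IR64. Their camera adjusted p = 0.0427 became an adjusted p = 0.610 with an estimated correlation. Fry called 4 of the 47 tested lists for the difference, among them the small heat shock proteins and the MADS box factors, both with an adjusted p = 0.0285, and not the other lists that camera called, whose adjusted p lay between 0.0522 for NAC and DREB factors and 0.290 for ribosomal proteins.

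For Apo minus IR64, 358 of 17727 probes passed the threshold, 137 positive and 221 negative. With the arrays scaled to 1 spread 247 passed, 239 of them among the 358. Ratios spread more widely on most Apo arrays, and this alone would part the genotypes for genes or lists with the same sign in both. The list tests were not run on scaled ratios, so its part in the list differences is unknown. With the replicate number as a block 951 passed, and then so did HSFA6B, HSFC1A, URO-D2, HSP17.9B, GSA, RPS21 and RPL18, while the lists of heat shock factors and of MADS box factors lost their calls (adjusted p = 0.0574 for each). Without IR64 replicate 1, whose correlations are given above, 5959 probes passed, all 358 among them. Without Apo replicate 1, 2 or 3 the numbers were 11, 9 and 12, without IR64 replicate 2 it was 5, and without IR64 replicate 3 limma called 0, with 2589 at an unadjusted p under 0.05. The calls for abscisic acid signalling, NAC and DREB factors and chlorophyll synthesis held with each array left out, but not those for small heat shock proteins (0.0521 without Apo replicate 2, 0.0903 without IR64 replicate 1), ribosomal proteins (0.0935 and 0.0746 without IR64 replicates 2 and 3), heat shock factors (0.0521, 0.0577 and 0.0818 without Apo replicates 2 and 3 and IR64 replicate 2) and MADS box factors (0.0752, 0.0577 and 0.125 without Apo replicates 2 and 3 and IR64 replicate 1). Calls were added for LEA proteins and dehydrins (0.0260 and 0.0358 without Apo replicate 1 and IR64 replicate 2), photosystem proteins (0.02445 and 0.0489 without Apo replicate 1 and IR64 replicate 1), and, without IR64 replicate 1, osmolyte enzymes (0.0489) and protein disulfide isomerases and ER chaperones (0.0427). With an estimated correlation on all arrays these lists had an adjusted p = 0.650, 0.807, 0.773 and 0.773. Camera called no list of markers of other cell types for the difference; the lowest adjusted p was 0.163, for anther markers.

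The last comparison asked how far the genotypes' responses were alike. Over both genotypes LEA proteins and dehydrins had a median ratio of 1.17 with all 6 members positive, abscisic acid signalling 16 positive and 2 negative probes of 21, photosystem proteins 10 negative and none positive of 11, and clock components 7 negative and none positive of 8. Single genes with 1 probe and large ratios of the same sign in both genotypes were, for example, OsPM19L1 at 1.96 in Apo and 1.77 in IR64, ELA3 at 1.63 and 1.42, and ADF-7 at -1.28 and -1.19. The ELA3 values of the genotypes did not overlap, with a difference of 0.208 (limma adjusted p = 0.0626). Camera gave these lists adjusted p = 0.00372 for both LEA proteins and abscisic acid signalling, 0.00501 for photosystem proteins and 0.0181 for clock components. With an estimated correlation none was called, with adjusted p = 0.376 for LEA proteins and clock components, 0.584 for abscisic acid signalling and 0.598 for photosystem proteins. All 4 were called by fry, which called 34 of the 47 tested lists for the mean, root markers (adjusted p = 0.00340) and vascular and secondary wall markers (0.00801) among them. With single arrays left out calls were added for lipid transfer proteins (0.0435 without Apo replicate 1), small heat shock proteins (0.0484 and 0.0486 without Apo replicate 1 and IR64 replicate 2) and MADS box factors (0.0487, 0.0436 and 0.0486 without Apo replicates 1 and 2 and IR64 replicate 2). With an estimated correlation on all arrays these lists had an adjusted p = 0.404, 0.376 and 0.376.

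For the mean of both genotypes 10305 of 17727 probes passed limma's test, 5193 positive and 5112 negative. Called positive in both genotypes were 2785 probes, where 989.2 would be shared by independent lists, and called negative in both were 2675, against 918.9, while 99 were called on opposite sides. Independence is not the value without a drought response here: with no dyes exchanged, a dye effect of single probes would by itself give shared calls and a correlation between the genotypes, and how much of either it accounts for was not tested. A difference in harvest day between stressed and control leaves, if there was any, could do the same and was not tested either. Of the 10305 probes, 6409 (62.2%) had the larger absolute ratio in Apo, with median absolute ratios of 0.243 in Apo and 0.199 in IR64. The SD over all annotated spots was also wider on the Apo arrays, 0.3166 to 0.3562, than on the IR64 arrays, 0.2674 to 0.3168. With the arrays scaled to 1 spread, 8454 probes were called in Apo and 8055 in IR64. A stronger response in Apo and a wider scale of its arrays cannot be told apart here. Of the 358 probes that differed between the genotypes, 193 had the same sign in both, 140 of these larger in Apo, and 161 had opposite signs. These are signs of mean ratios with no threshold, so opposite signs include genes near 0 in 1 genotype, such as DREB1B in Apo. Across probes, which are not independent replicates, the mean ratios of Apo and IR64 correlated at 0.829 by Pearson's and 0.739 by Spearman's coefficient. Without IR64 replicate 1 Pearson's coefficient was 0.722.

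**Figure D3:**
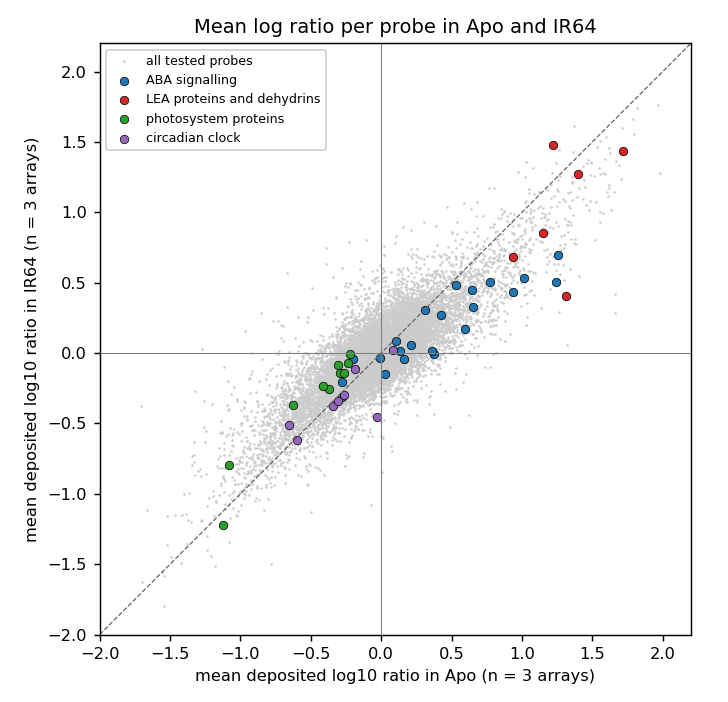
Mean deposited log10 ratio of each of 17727 tested probes in Apo (n = 3 arrays) and IR64 (n = 3 arrays), with members of 4 gene lists in colour and the line of equal ratios dashed. All 6 LEA and dehydrin probes lie on the positive side in both genotypes, and the probe of CAB2R lies at -1.12 in Apo and -1.22 in IR64.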

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

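The comparison of probe positions between the genotypes, the test of a shared replicate batch, the test of row numbers and the regroupings of the arrays were chosen after the results were seen. The slope test and the test of probes large on 1 array were written before their own values were seen. Both followed the array correlations that prompted them.

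The ratios of 358 probes differed between Apo and IR64 by limma's test of the difference itself. Only 50 of them passed the rule for named genes. Among these the largest differences, Apo minus IR64 on the log10 scale, were 1.38 for GER2, 0.851 for DREB1B, 0.774 for ARF16, 0.615 for MADS14, 0.604 for chia4a, 0.602 for DREB1A, 0.589 for HOX24 and 0.564 for SAPK1 on the positive side. On the negative side they were -1.33 for LIS, -1.14 for PAL06, -0.755 for BURP17, -0.697 for CAD6, -0.654 for ETR3, -0.617 for rpl5, -0.597 for OsCiTrx and -0.543 for URH2. Smaller positive differences past the same threshold were those of SGR, which starts chlorophyll breakdown, at 0.490, OsC3H2 at 0.391, the nicotianamine synthase NAS1 at 0.380, MADS58 at 0.378 and the zinc transporter OsZIP4 at 0.30. Smaller negative differences were those of ORC5, of the DNA replication origin complex, at -0.542, the metal transporter NRAMP4 at -0.482, AOS, an enzyme of jasmonate synthesis, at -0.373, the metallothionein MT2C at -0.359 and the glutaredoxin GRXS2 at -0.312. Other probes of NRAMP4, MT2C and GRXS2 were not past the threshold. The median differences of the gene lists that camera called were 0.228 for NAC and DREB factors, 0.197 for abscisic acid signalling, 0.153 for heat shock factors, 0.0815 for MADS box factors, 0.0770 for small heat shock proteins, -0.202 for cytosolic ribosomal proteins and -0.216 for chlorophyll synthesis. With an estimated correlation camera called 0 of these 7, and the lowest adjusted p was 0.610.

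Of the 10 splits of the 6 arrays into 3 and 3, only the real one gave as many as 358 probes, and the highest other split gave 1. Among the 4 splits that part all 3 replicate pairs the real one was the highest, and the 6 that part 1 pair gave at most 1. With 10 splits the share cannot fall under 0.1, so these splits are too few. The same holds for the 4 ways of turning the signs of 3 arrays: only the real one, 1 of 4, gave the 8890 probes of Apo or the 7619 of IR64, and the highest other gave 0. For the mean of both genotypes, 1 of 32 ways of turning the signs gave as many as 10305 probes, the real one, and the highest other gave 358. With the replicate numbers taken to pair the arrays, which the labels do not state, only 4 of these ways turn each pair together. These are again too few, and the highest other of them gave 0.

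The IR64 replicate 1 array lay nearer to the Apo arrays, with correlations of 0.832 to 0.894, than to the other IR64 arrays, with 0.755 to 0.767, and without it 5959 probes differed between the genotypes. Whether both channels held Apo RNA under a wrong label stays open. On probes that part Apo from the other IR64 arrays, this array reached the IR64 level on at least 13.5%. Each Apo array held out did so on 1.89% to 5.25%. Its median position on these probes was 0.302 to 0.361 of the way, against -0.0551 to 0.159 for Apo arrays. Its lowest slope towards the other IR64 arrays, 0.336 against at most 0.207 for an Apo array, left the question open. Its correlations with the Apo arrays overlapped those among the Apo arrays, 0.865 to 0.928. The share was chosen after the results were seen and can grow with an array's own scatter, so it does not decide. RNA of the other genotype in 1 channel stays open as well. On this array 4 probes were large and near 0 elsewhere, against 13, 15 and 1 on the Apo arrays and 1 and 0 on the other IR64 arrays. That is fewer than the highest of the others but the most of the IR64 arrays, so the test does not decide. The Apo replicate 1 deviation followed that of IR64 replicate 1 with a slope of 0.229 and 10.3% of the variance. A batch shared by the replicate 1 arrays need not act equally on both genotypes, so these values do not limit its part, which stays open. A mixture of RNAs in both channels, milder or more severe stress of these plants, and a technical fault of this array also stay open, and no biological explanation was tested.

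Among the 4715 spots with no gene in the annotation, which enter none of the comparisons, 478 (10.1%) had a mean ratio above 1, against 137 (0.767%) of the annotated ones. Their median was 1.48, 1.91 and 1.42 on the Apo arrays and 1.72, 1.96 and 1.35 on the IR64 arrays, with 235 and 220 of them above 2 on the replicate 2 arrays and at most 32 on any other. They recurred at short steps through the table: 96.2% of the steps between successive ones were of at most 8 numbers, where the highest of 1000 random draws of as many unannotated spots gave 22.6%. That is consistent with control spots placed at regular positions, which a scatter of plant genes would not give. What they contain is not given in the sources used here, and no biological explanation was tested.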

How the results depend on the processing

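Testing all spots of the table was chosen after seeing the data; the other alternatives were planned. Centring and scaling left the counts for Apo, IR64 and the mean within 1.5 times the reported ones, and so did robust eBayes, unmoderated tests, array weights, the replicate block, averaging per gene, probes with no 0, all spots and, for Apo and IR64, each genotype fitted alone. A 2-fold minimum, which holds only if the base is 10, lowered them by construction, to 4184, 3141 and 3490. With single arrays left out the Apo count ranged from 6650 to 10179, the IR64 count from 5076 to 8457, the count for the mean from 8730 to 10899 and Pearson's correlation from 0.722 to 0.863. The count of 358 for the difference was less stable: unmoderated tests gave 86, array weights 8559, the replicate block 951 and all spots 235, and with single arrays left out it ranged from 0, without IR64 replicate 3, to 5959, without IR64 replicate 1; the cause was not tested. Of the unmoderated calls 47 were among the 358, and of the array weights and replicate block calls 358 and 317. The array weights were lowest for IR64 replicate 1, at 0.1485, and highest for Apo replicate 3, at 5.055. Centring alone changed no call of a named gene or list. The mean of DREB1A in Apo, not past the threshold, turned to -0.107 without Apo replicate 1, whose own value was the only positive one, and reached 0.0734 without Apo replicate 3. With the block, besides the calls given in the report, the anther marker MTR1 lost its call in Apo, and no other call of a named gene or list changed. The counts with the block were 9807 for Apo, 8626 for IR64 and 11139 for the mean. Of the 35 named probes of the difference 17 were called, and of these 14 to 17 lost their call without any 1 array other than IR64 replicate 1; without that array none did, and 17 of the other 18 gained one. With an estimated correlation camera called 0 lists in every comparison. Probes near background could not be told from others, since intensities were not used here.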

Other observations

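The test of the sign was written before its value was seen, and none in this part was chosen afterwards.

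Members of several gene groups passed the threshold in both genotypes although camera called none of these lists on all 6 arrays. Over all tested probes 8890 of 17727 passed in Apo and 7619 in IR64. Calls among the members of a list therefore do not by themselves set it apart. Of 22 probes for nitrogen assimilation, 9 were negative and 6 positive in Apo and 8 and 4 in IR64. The ammonium transporter AMT1 stood at -0.919 in Apo and -0.751 in IR64, and Fd-GOGAT, which makes glutamate in the light, at -0.737 and -0.659, and the nitrate transporter NRT2.3 at -0.662 and -0.615. The list median in Apo was 0.0185 and its mean -0.162. In photorespiration GDCSH, of the glycine cleavage system, was at -0.895 and -0.831 and the glycolate oxidase GLO5 at -0.685 and -0.614, although a second GLO5 probe was not past the threshold and the probes of GLO1 went both ways. Of 21 probes for cytokinin response, activation and breakdown, 8 were negative and 1 positive in Apo and 7 and 1 in IR64, with OsRR9 at -0.581 and -0.312. Diterpenoid phytoalexin enzymes had 5 negative probes of 13 in Apo and 7 in IR64 and none positive, led by CPS2 at -0.932 and -0.679.

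Metallothioneins, small metal-binding proteins, went both ways: MT21A was positive at 1.35 in Apo and 1.25 in IR64, and MT2B negative at -1.56 and -1.55 on 1 probe, while its second stood at -0.175 in Apo and, not past the threshold, at 0.0852 in IR64. Sugar metabolism was mixed as well, with the sucrose synthase OsSUS4 at 1.15 and 1.03 and the sucrose phosphate synthase OsSPS2 at -0.493 and -0.657, and of 35 probes for sucrose and starch metabolism 8 were positive and 10 negative in Apo and 9 and 8 in IR64. In chlorophyll breakdown SGR stood at 0.402 in Apo and -0.0887 in IR64 and NYC1 at 0.330 and -0.104; both were called in Apo, and SGR for the difference, while the third gene of the list, negative in Apo at -0.133 and not past the threshold in IR64 at -0.107, entered it by the synonym Lls1 and is otherwise named CAO, after an enzyme of chlorophyll b synthesis, so it says nothing sure on breakdown. Camera called none of these lists that had enough probes, with adjusted p in Apo of 0.747 for nitrogen assimilation, 0.389 for photorespiration, 0.181 for cytokinin, 0.108 for phytoalexins, 0.687 for metallothioneins and 0.733 for sucrose and starch; in IR64 the phytoalexin list had 0.0778, and 0.0494 without Apo replicate 2, against an adjusted p = 0.362 with an estimated correlation on all arrays. Fry, which does not compare a list with other genes, called all 6 in both genotypes, among 33 of 47 lists in Apo and 29 in IR64, with adjusted p between 3.9e-05 for metallothioneins in Apo and 0.00312 for nitrogen assimilation in IR64.

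The labels put control RNA in the Cy5 channel, and Feature Extraction writes red over green, so a positive ratio would mean a higher level in the well-watered leaves. The LEA and dehydrin probes, of a class known to accumulate in drying leaves, had a median deposited ratio of 1.17 over both genotypes with all 6 on the positive side, which argues against that reading. Limma's camera gave this list an adjusted p = 0.00372, and an adjusted p = 0.376 with an estimated correlation. A candidate explanation is that the deposited ratios are drought over control; whether the ratio was turned before deposit or the dyes were assigned otherwise than the labels say stays open, as neither was tested.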
